A study of Arabidopsis thaliana with 8 samples.

How the data were processed

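RNA was sequenced from 8 libraries of 12-day-old seedlings grown on plates at 22 °C under 16 h light and 8 h dark, with single-end reads of 50 bp, per the labels' protocols. The genotypes were wild type Col-0, hag1, ada2b and scs1 scs2a with 2 libraries each, grouped by the labels' titles. The deposited table gives, for 32548 genes, one normalised count signal per library, which is not a whole number and is not pooled. The submitters' processing notes name HISAT2, edgeR and the TAIR10 build, with no versions, and the counter, the annotation, any filter and the use of strand are not given in the sources used here. Low values of the deposited signal lay close to whole multiples of a step per library. The value of 1 read, estimated from these steps, was 0.951 to 1.09, and 92.6 to 100% of low values came within 0.1 of a whole number of reads. Because the values shift from the step by gene, whole reads were not taken as recovered and no count model was run. The plan made before the data were examined assumed whole-number counts, and its written fallback for other values was used in its place. Depth was even, at 20570967 to 22344725 normalised counts per library, and counting intervals (95%, exact Poisson ratio of estimated reads) and floors cover counting error only.

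Values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3. Genes with a value of 1 or more in at least 2 libraries were kept, which left 25459. By the estimated steps, 1 read passed this filter in both wild type libraries and failed in both scs1 scs2a libraries. Genes near 1 read were thus kept more easily through wild type. One model with genotype as its only term was fitted over the 8 libraries, so that the 4 genotypes shared 1 estimate of the spread (4 residual degrees of freedom, 4.42 prior degrees of freedom), with limma's trend on mean level. The 3 comparisons with wild type and the 3 between mutants were contrasts of this model, with two-sided tests and Benjamini-Hochberg adjustment over all genes at 0.05 and no fold minimum. All 32548 identifiers matched the reference table of TAIR10.1, and 10804 had a symbol there. Symbols come from that table and no coordinates are printed, because the builds differ by name. None of the columns of the table went unused. Libraries of a genotype differed by more than counting noise, with mean squared differences 4.3 to 6.3 times the counting variance, so none was treated as a duplicate.

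There were 25 gene lists, with 411 genes in all. They cover SAGA subunits, photosystem antenna, photosystem core and rubisco small subunit, flavonoid synthesis, early auxin, cold, abscisic acid, salicylic acid and defence, jasmonate and wounding, heat shock, wax, glucosinolate synthesis, iron deficiency, phosphate starvation, flowering and floral identity, meristem, cell division, trichome fate, ribosomal proteins, circadian clock, root markers, seed storage, senescence, cell wall expansion, and touch and handling. Each list with at least 5 tested members was tested with limma's camera at a preset correlation of 0.01 and adjusted over 75 tests, with camera at an estimated correlation and fry as alternatives. With an estimated correlation no list was called, and the smallest adjusted p was 0.62, while fry, which does not compare a list with other genes, called 19, 17 and 10 lists in hag1, ada2b and scs1 scs2a. Camera at the preset correlation called 7 higher and 6 lower in hag1, 2 and 7 in ada2b, and 5 and 5 in scs1 scs2a.

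The rule for naming genes took the targeted genes and, per mutant, the 8 largest rises and 8 largest falls among called genes that have a symbol, a mean log2 CPM of at least 1 (values scaled to the library total) and both mutant libraries beyond both wild type libraries. It added up to 4 members by adjusted p of each list that camera called or that had at least 3 called members, the 4 largest differences each way per mutant pair, and the 5 genes each way with the smallest adjusted p in all 3 mutants. It named 207 genes. MYB51 and CCA1 lie outside the rule and were chosen after their values were seen. Likeness between mutants was set beside independent lists and 100 simulations of unchanged groups that shared 2 simulated wild type libraries. The gene fit and the list test were tested on simulated data for the comparisons with wild type, with 200 changed genes per comparison. Changed genes had means of 10 or more, and all genes had the same spread between replicates (dispersion 0.00173). The shares below hold for this setting, which has fewer changed genes than were called in the data. Of the changes of 0.5, 1 and 2 on the log2 scale, 62.1, 80.6 and 100% were called for hag1 (25458 genes), 68.2, 89.6 and 98.5% for ada2b (25452 genes) and 66.7, 92.5 and 95.5% for scs1 scs2a (25471 genes), with 4, 10 and 0 unchanged genes called. Alternatives were median-ratio and upper-quartile scaling, 3 other filters on low values, a pseudocount of 0.1, a replicate block, a fold minimum of 2, fits of only the 2 genotypes compared, and leaving out each library. A filter at 10 and a robust spread estimate were added after seeing the data.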

Results

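Gene expression was measured by RNA sequencing in 12-day-old Arabidopsis seedlings of 4 genotypes, namely wild type Col-0, hag1, ada2b and scs1 scs2a, with 2 libraries each. HAG1 is a histone acetyltransferase and ADA2B its adaptor protein, both subunits of the transcriptional coactivator complex SAGA. The scs1 scs2a plants carried mutations in a pair of genes, per the labels. The series asks which features of SAGA plants share with other organisms and which are their own, and each mutant was compared with wild type and with the other mutants. The 8 libraries held totals of 20570967 to 22344725 normalised counts, which correspond to an estimated 20517756 to 22042999 reads. The 10 most abundant genes took 4.51 to 5.59% of a library. Of 32548 genes, 25459 were tested. The first principal component held 40.7% of the variance, with the wild type libraries at -0.51 and -0.52 and the ada2b libraries at 0.43 and 0.45. The second held 28%, with the hag1 libraries at 0.59 and 0.57. The labels do not say whether libraries of a genotype came from separate cultures, so p-values measure the spread between these samples, which may be technical. Gene values below are mean normalised counts ± SD (n = 2 per genotype), and log2 fold changes are on the log2(value + 1) scale ± SE. The gene lists and the rule for naming genes were chosen before the data were examined, and the list tests between mutants were added after seeing the data. Those tests between mutants were not rerun with another scaling, a replicate block or a library left out.

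The targeted genes were examined first. HAG1 (AT3G54610) stood at 312 ± 22.8 in wild type and 132 ± 1.35 in hag1, a log2 fold change of -1.23 ± 0.09 (limma adjusted p = 2.92e-05). It was higher in ada2b, at 415 ± 29.5 (log2 fold change 0.41 ± 0.09, limma adjusted p = 0.00598), and stood at 345 ± 0.0073 in scs1 scs2a (limma adjusted p = 0.3). ADA2B (AT4G16420) stood at 710 ± 2.64 in wild type, 641 ± 46.2 in hag1, 590 ± 33 in ada2b and 702 ± 12.9 in scs1 scs2a. Its log2 fold change in ada2b was -0.27 ± 0.07 (limma adjusted p = 0.0136). This call ended without wild type replicate 1 (adjusted p = 0.0516), wild type replicate 2 (0.0567) or ada2b replicate 1 (0.0886). Reads from outside an insertion can remain in a mutant, so ADA2B is a weak check of the ada2b labels. SCS1 and SCS2A were not analysed here by name.

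In hag1, camera at its preset correlation called the phosphate starvation list as higher and the iron deficiency, photosystem, cold and abscisic acid lists as lower. No list was called in any mutant with an estimated correlation (smallest adjusted p = 0.62). With 4 residual degrees of freedom that option is weak, so a missing call does not show that a list was unchanged. The 8 largest rises by the naming rule included DIN2 (AT3G60140), a dark-inducible beta-glucosidase, which went from 9.71 ± 3.07 in wild type to 589 ± 99.2, a log2 fold change of 5.8 ± 0.35 (limma adjusted p = 1.42e-05). TH8 (AT1G69880), a thioredoxin, rose from 33.4 ± 3.38 to 984 ± 21.5, and BAM5 (AT4G15210), a beta-amylase, from 208 ± 85.2 to 4600 ± 1470. CEP1, a cysteine endopeptidase, GAT1_2.1, LHT7, ACS7, an enzyme of ethylene synthesis, and GDPD6 rose by 4.25, 3.4, 3.36, 3.23 and 3.2 on the log2 scale. Among the falls, PPT2 (AT3G01550), a plastid phosphoenolpyruvate translocator, went from 301 ± 0.226 to 5.59 ± 2.38, a log2 fold change of -5.57 ± 0.3 (limma adjusted p = 8.59e-06). The iron deficiency regulators BHLH100 and bHLH38 had log2 fold changes of -5.15 ± 0.32 and -4.04 ± 0.56. SCPL13 fell by 4.55 and CYP707A2, an enzyme of abscisic acid breakdown, by 4.44. EXLB1 fell by 4.22, HPL1, a hydroperoxide lyase, fell by 4.2, and FMO GS-OX2, which oxidises glucosinolate side chains, fell by 4.16.

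Of the 15 phosphate starvation genes tested in hag1, 13 rose and the other 2 did not pass, and 13 changed when adjusted over the list alone (median log2 fold change 1.62, camera adjusted p = 2.27e-08, adjusted p = 0.62 with an estimated correlation). SRG3, a glycerophosphodiester phosphodiesterase, rose from 1900 ± 124 to 7620 ± 0.118, and PLDP2, MGD2 and the sulfolipid enzyme SQD1 rose by 2.04, 1.69 and 1.3 on the log2 scale. Beside these, 6 of 22 root markers rose and 1 fell, 6 changing when adjusted over the list alone (median 0.25, camera adjusted p = 0.0759, adjusted p = 0.726 with an estimated correlation). The root markers were called without wild type replicate 2 (adjusted p = 0.0408) or hag1 replicate 2 (0.000284). They included PYK10, a beta-glucosidase of roots, at 43000 ± 1090 in wild type and 73000 ± 13300 in hag1. Of the 22 iron deficiency genes, 16 fell and 2 rose, and 18 changed when adjusted over the list alone (median -1.16, camera adjusted p = 8.49e-05, adjusted p = 0.62 with an estimated correlation). The regulator bHLH39 and the iron transporter OPT3 fell by 4 and 1.04, while the iron store FER1 rose by 1.77 ± 0.06, from 1580 ± 0.685 to 5410 ± 476.

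The photosystem core and rubisco small subunit list fell in hag1, with 24 of 25 members lower and 24 changed when adjusted over the list alone (median -0.57, camera adjusted p = 4.02e-09, adjusted p = 0.62 with an estimated correlation). PSAL, a subunit of photosystem I, went from 36900 ± 980 to 20700 ± 1060, and PSAO and PSAG had log2 fold changes of -0.84 and -0.83. Of 17 antenna genes 9 were lower and 1 higher, with 13 changed when adjusted over the list alone (median -0.38, camera adjusted p = 0.0347, adjusted p = 0.708 with an estimated correlation). LHCA3 fell by 0.74 ± 0.11, and the near-identical antenna and rubisco small subunit copies, such as RBCS3B (-0.96 ± 0.1), are uncertain as single genes. The antenna call ended without wild type replicate 1 (adjusted p = 0.258) or hag1 replicate 1 (0.104).

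Cold response genes fell in hag1, with 8 of 13 lower, 2 higher and 10 changed when adjusted over the list alone (median -1.46, camera adjusted p = 0.00339, adjusted p = 0.62 with an estimated correlation). COR15A, which protects chloroplasts in the cold, went from 5630 ± 562 to 1150 ± 573, and LTI78 fell by 1.79 on the log2 scale. Of 13 abscisic acid response genes, 9 fell and 2 rose, with 11 changed when adjusted over the list alone (median -1.48, camera adjusted p = 0.0144, adjusted p = 0.62 with an estimated correlation). The phosphatases HAI2 and PP2CA fell by 3.84 and 1.56, RD20 fell by 3.77 and NCED3, an enzyme of abscisic acid synthesis, fell by 1.54. Without wild type replicate 2 this list was not called (adjusted p = 0.057). All 22 glucosinolate synthesis genes tested changed in hag1, 16 lower and 6 higher, and 22 changed when adjusted over the list alone (median -0.43, camera adjusted p = 0.00717, adjusted p = 0.62 with an estimated correlation). MYB28 and MYB29, regulators of the methionine-derived branch, fell by 0.94 and 2.53, and its enzymes MAM1 and CYP83A1 fell by 1.29 and 0.7. CYP83B1 and SOT16, which act in the tryptophan-derived branch, were higher by 0.58 ± 0.07 and 0.48 ± 0.06.

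Of the 14 touch and handling response genes, 9 rose in hag1 and 11 changed when adjusted over the list alone (median 1.42, camera adjusted p = 0.000208, adjusted p = 0.62 with an estimated correlation). The calmodulin-like TCH3 rose from 598 ± 49.2 to 3190 ± 150, and WRKY18 and RHL41 rose by 2.3 and 2.71. Flavonoid synthesis genes were higher in 7 of 18 cases, with 7 changed when adjusted over the list alone (median 0.63, camera adjusted p = 0.00167, adjusted p = 0.62 with an estimated correlation), led by F3H (1.27 ± 0.12) and FLS1 (1.07 ± 0.11). Of 15 cytosolic ribosomal protein genes 9 rose, and 11 changed when adjusted over the list alone (median 0.21, camera adjusted p = 0.00167, adjusted p = 0.62 with an estimated correlation), among them STV1 at 0.45 ± 0.07. Senescence genes were higher in 6 and lower in 1 of 11 cases, with 7 changed when adjusted over the list alone (median 0.48, camera adjusted p = 0.0185, adjusted p = 0.62 with an estimated correlation), and the senescence regulator NAC6 rose from 132 ± 14.3 to 441 ± 7.15. Salicylic acid and defence genes rose in 8 of 19 cases, 8 changing when adjusted over the list alone (median 0.49, camera adjusted p = 0.0326, adjusted p = 0.62 with an estimated correlation), including SARD1 at 1.45 ± 0.12. Heat shock genes were higher in 9 and lower in 1 of 17 cases, with 13 changed when adjusted over the list alone (median 0.62, camera adjusted p = 0.0435, adjusted p = 0.62 with an estimated correlation), and HSP90.1 rose by 0.62 ± 0.1. The defence call ended without wild type replicate 2 (adjusted p = 0.0791), and the heat shock call without wild type replicate 1 (0.126), hag1 replicate 1 (0.074) or hag1 replicate 2 (0.0783).

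The remaining lists were not called by camera in hag1. Higher and lower members, those changed when adjusted over the list alone and the camera adjusted p were 4, 8, 13 and 0.196 for early auxin response and 3, 8, 11 and 0.196 for the circadian clock. They were 7, 4, 11 and 0.324 for jasmonate and wounding, 4, 4, 10 and 0.445 for flowering and floral identity, and 3, 5, 8 and 0.451 for cell wall expansion. They were 5, 3, 8 and 0.462 for SAGA subunits and 1, 3, 6 and 0.214 for trichome fate. Of 7 wax genes 2 were higher and 3 lower, with 5 changed when adjusted over the list alone (adjusted p = 0.977). In 16 cell division genes 3 were higher and 3 changed when adjusted over the list alone (adjusted p = 0.166), and in 10 meristem genes 1 was higher, 1 lower and 2 changed when adjusted over the list alone (adjusted p = 0.991). None of 7 seed genes passed limma's test, with or without being adjusted over the list alone (camera adjusted p = 0.509). Single members moved far. MAF5 and MAF4, relatives of the floral repressor FLC, fell by 3.33 and 2.42, the floral promoter AGL20 fell by 1.47 and the expansin EXPA8 fell by 2.43. LHY, a morning clock gene, rose from 51.7 ± 0.803 to 252 ± 16.7, and the evening genes PRR3 and FKF1 fell by 2.09 and 1.78. The auxin response gene IAA6 had an estimated 2 reads in hag1 against an estimated 34 in wild type, a ratio of 0.0567 (95% counting interval 0.0066 to 0.221). In all, 5419 genes were higher and 5860 lower in hag1, of which 1276 and 1695 changed at least 2-fold.

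**Figure D1:**
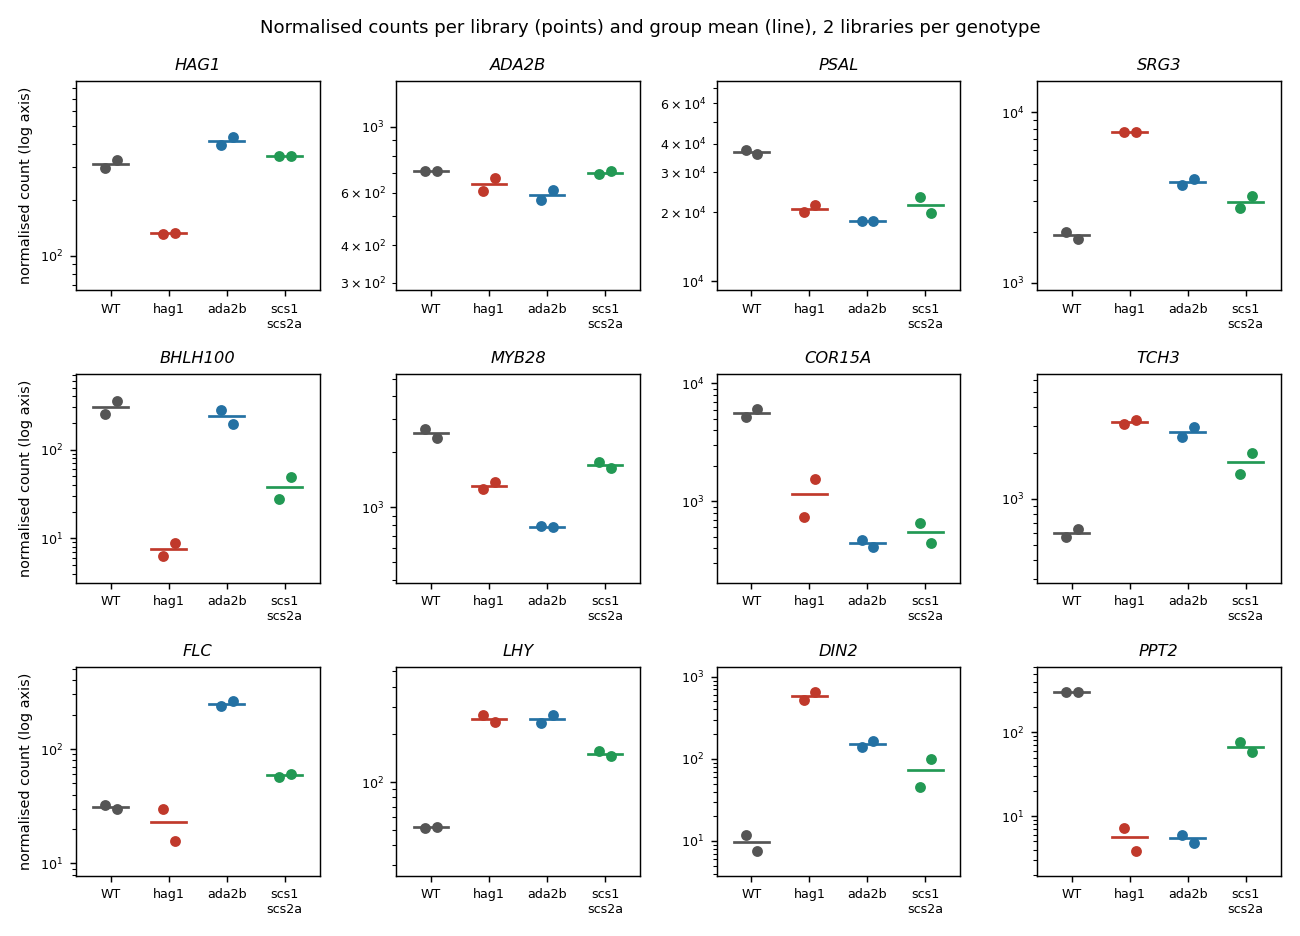
Normalised counts (log axis) of 12 named genes in each library (points, 2 per genotype) with the genotype mean (line). SRG3 was higher in each mutant library than in wild type and COR15A lower, while BHLH100 stood at 7.56 in hag1 and 240 in ada2b.

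In ada2b, falls of at least 2-fold outnumbered such rises. At its preset correlation camera called the glucosinolate synthesis, photosystem and cold lists as lower and the touch list as higher, and it called none with an estimated correlation (smallest adjusted p = 0.62). DIN2 rose from 9.71 ± 3.07 to 152 ± 20.1 (log2 fold change 3.86 ± 0.35, limma adjusted p = 6.54e-05). FLC (AT5G10140), a repressor of flowering, stood at 31.2 ± 1.88 in wild type and rose by 2.95 ± 0.28 on the log2 scale (limma adjusted p = 7.8e-05). ACS7, the peroxidase PRXCA, the zinc finger gene STZ, GH9A3, RAV2 and SZF1 rose by 2.82, 2.72, 2.67, 2.63, 2.53 and 2.48 on the log2 scale. FMO GS-OX2 fell from 506 ± 86.4 to 7.87 ± 4.06, a log2 fold change of -5.9 ± 0.46 (limma adjusted p = 3e-05), and GolS2, which makes galactinol, had one of -5.89 ± 0.69. CYP707A2, PPT2, PCC1, CSLB03, CORI3 and DAA1 had log2 fold changes of -5.8, -5.56, -5.3, -5.17, -5.02 and -4.99.

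Of the 22 glucosinolate synthesis genes, 17 fell and 3 rose in ada2b, and 21 changed when adjusted over the list alone (median -0.77, camera adjusted p = 1.81e-06, adjusted p = 0.62 with an estimated correlation). MYB28 went from 2520 ± 184 to 783 ± 12.1, and MAM1, CYP83A1 and the transporter BAT5 fell by 1.82, 1.55 and 1.49. The 3 that rose were MYB51, CYP83B1 and SOT16 of the tryptophan-derived branch, at 1.2 ± 0.21, 0.6 ± 0.07 and 0.42 ± 0.06. Photosystem core and rubisco small subunit genes fell in 23 of 25 cases, 23 changing when adjusted over the list alone (median -0.54, camera adjusted p = 4.3e-08, adjusted p = 0.62 with an estimated correlation). PSAL went from 36900 ± 980 to 18300 ± 38.3. Antenna genes fell in 15 of 17 cases, 16 changing when adjusted over the list alone (median -0.89, camera adjusted p = 1.56e-05, adjusted p = 0.62 with an estimated correlation), including LHCB3 (-1.6 ± 0.18) and LHCA1 (-1.05 ± 0.12).

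Cold response genes fell in 9 and rose in 1 of 13 cases in ada2b, with 10 changed when adjusted over the list alone (median -1.36, camera adjusted p = 0.000745, adjusted p = 0.62 with an estimated correlation). COR15A went from 5630 ± 562 to 440 ± 48, and KIN1, ERD10 and COR47 fell by 2.27, 1.43 and 1.36. Abscisic acid response genes fell in 9 and rose in 2 of 13 cases, 12 changing when adjusted over the list alone (median -1.27, camera adjusted p = 0.0191, adjusted p = 0.62 with an estimated correlation). RD20 fell by 4.69 and HAI2 fell by 3.62, while the transcription factor RD26 rose by 1.48. Of 14 touch response genes 9 rose, with 9 changed when adjusted over the list alone (median 1.36, camera adjusted p = 0.00167, adjusted p = 0.62 with an estimated correlation), TCH3 from 598 ± 49.2 to 2760 ± 312. SAGA subunit genes rose in 11 and fell in 1 of 20 cases, with 14 changed when adjusted over the list alone (median 0.25, camera adjusted p = 0.0062, adjusted p = 0.62 with an estimated correlation). They included SGF11 at 0.52 ± 0.08 and TAF6B at 0.38 ± 0.05, and the member that fell was ADA2B. Among all genes with a mean of 100 or more, 34.9% rose in ada2b (median 0.11), and list members were not matched to other genes by level. Cell division genes fell in 7 of 16 cases, 7 changing when adjusted over the list alone (median -0.17, camera adjusted p = 0.0267, adjusted p = 0.62 with an estimated correlation). CYCD3;1, a cyclin that drives division, fell from 586 ± 7.76 to 207 ± 12.7, and the mitotic kinase CDKB2;2 fell by 0.88. Trichome fate genes fell in 4 of 9 cases, with 4 changed when adjusted over the list alone (median -0.66, camera adjusted p = 0.0335, adjusted p = 0.62 with an estimated correlation), EGL3 by -1.35 ± 0.18. The abscisic acid call ended without wild type replicate 2 (adjusted p = 0.0645), and the trichome call without wild type replicate 2 (0.0639) or ada2b replicate 1 (0.0627).

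The other lists were not called by camera in ada2b. Higher and lower members, those changed when adjusted over the list alone and the camera adjusted p were 9, 4, 13 and 0.0759 for phosphate starvation, 2, 7, 9 and 0.0759 for iron deficiency and 3, 7, 10 and 0.301 for flavonoid synthesis. They were 3, 8, 11 and 0.143 for early auxin response, 4, 10, 16 and 0.128 for the circadian clock and 2, 6, 8 and 0.239 for salicylic acid and defence. They were 4, 8, 12 and 0.399 for jasmonate and wounding, 3, 6, 10 and 0.212 for flowering and floral identity, and 2, 4, 6 and 0.214 for cell wall expansion. They were 3, 1, 4 and 0.598 for heat shock. Phosphate starvation was called without wild type replicate 1 (adjusted p = 0.0479) or ada2b replicate 2 (0.0419), iron deficiency without wild type replicate 1 (0.0102) or ada2b replicate 1 (0.0238), and flavonoid synthesis without wild type replicate 1 (0.0268). Of 15 ribosomal protein genes 3 rose by limma and none changed when adjusted over the list alone (camera adjusted p = 0.152, and 0.0127 without ada2b replicate 2). In 7 seed genes 1 fell, and 1 changed when adjusted over the list alone (adjusted p = 0.399). The median, mean and test differed in sign for root markers (median 0.1, mean -0.14, test up, adjusted p = 0.859, with 5 higher, 3 lower and 7 changed when adjusted over the list alone). They also differed for meristem genes (0.1, -0.15, down, 0.436, with 4 lower and 4 when adjusted over the list alone). The same held for senescence (0.13, -0.13, up, 0.994, with 1 higher, 4 lower and 5 when adjusted over the list alone) and wax (-0.35, -0.11, up, 0.847, with 3 higher, 3 lower and 6 when adjusted over the list alone). Within these lists KCS6, of wax synthesis, rose from 6340 ± 105 to 17400 ± 103, EXPA1 rose by 1.03 ± 0.06, and PR5 and PAD3, of pathogen defence, fell by 2.55 and 1.76. AGL20 fell by 1.41, and FT fell by 1.25, a call that ended without wild type replicate 1 (adjusted p = 0.053), wild type replicate 2 (0.0568) or ada2b replicate 1 (0.087). The nicotianamine synthase NAS2 had an estimated 2 reads in ada2b against an estimated 152 in wild type, a ratio of 0.0124 (95% counting interval 0.00149 to 0.0457).

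In ada2b 6283 genes were higher and 5968 lower, of which 644 and 2940 changed at least 2-fold. The side with more genes depended on the scaling, with 5208 higher and 6463 lower under median-ratio scaling and 5290 and 6393 under upper-quartile scaling. Genes of low level fell more often. Among 6877 genes with a mean of 3 to 100, 28.8% fell and 8.33% rose (median log2 fold change -0.28), and among 16247 genes with a mean of 100 or more, 22.9% fell and 34.9% rose (median 0.11). Of the 6877 genes of low level, 1253 fell and 854 rose in hag1, and 479 fell and 245 rose in scs1 scs2a.

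**Figure D2:**
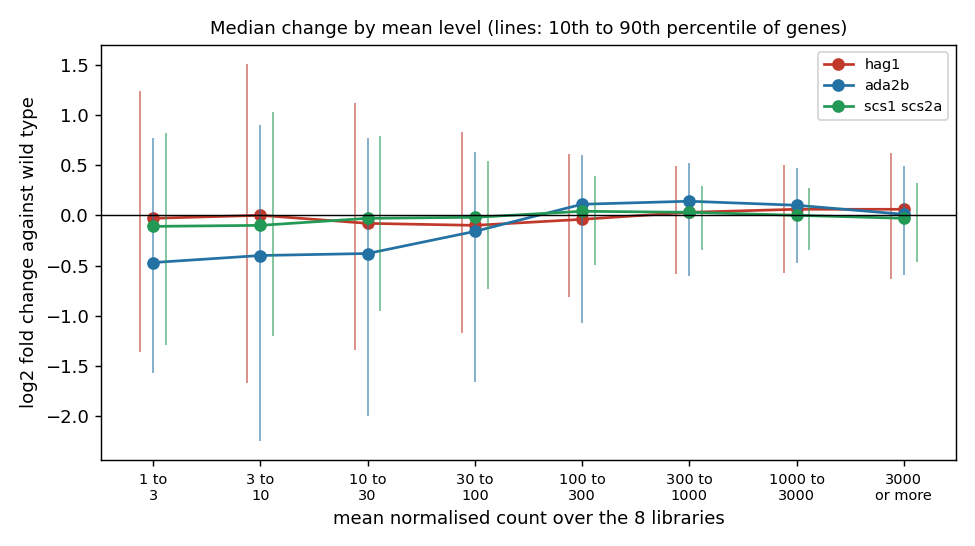
Median log2 fold change against wild type (points) by mean normalised count over the 8 libraries, with lines from the 10th to the 90th percentile of genes. The ada2b medians were -0.47 to -0.16 for means from 1 to 100 and 0.01 to 0.14 above. For means from 1 to 3 the filter kept genes at 1 read more easily through wild type, which can lower the medians.

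In scs1 scs2a, changes were smaller than in the other mutants. At its preset correlation camera called the photosystem, cold and clock lists as lower and the phosphate starvation and root marker lists as higher, and it called none with an estimated correlation (smallest adjusted p = 0.62). The SD of log2 fold changes with the error taken out was 0.47, against 0.75 in hag1 and 0.81 in ada2b. The cytochrome P450 gene CYP71B22 (AT3G26200) rose from 40.4 ± 4.63 to 276 ± 10.5, a log2 fold change of 2.74 ± 0.18 (limma adjusted p = 0.000168). DIN2 rose by 2.71 ± 0.35 (limma adjusted p = 0.00193), and CRK30, LHT7, HR4, CYP706A2, ACS7 and PRXCA by 2.4, 2.37, 2.22, 2.16, 2.09 and 2.06. COR15A fell from 5630 ± 562 to 549 ± 149, a log2 fold change of -3.38 ± 0.31 (limma adjusted p = 0.000563). DAA1, RD20, CYP707A2, BHLH100, MBP1 and AGL87 had log2 fold changes of -3.12, -3.1, -3.07, -2.99, -2.88 and -2.41. GolS2 fell by 2.44 ± 0.69, a call that ended without wild type replicate 1 (adjusted p = 0.108), wild type replicate 2 (0.123) or scs1 scs2a replicate 2 (0.243).

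Photosystem core and rubisco small subunit genes fell in 21 of 25 cases in scs1 scs2a, 25 changing when adjusted over the list alone (median -0.46, camera adjusted p = 4.08e-12, adjusted p = 0.62 with an estimated correlation), PSAL from 36900 ± 980 to 21600 ± 2370. Antenna genes fell in 13 of 17 cases, 15 changing when adjusted over the list alone (median -0.77, camera adjusted p = 2.52e-08, adjusted p = 0.62 with an estimated correlation), LHCA1 by -0.93 ± 0.12. Beside these falls, root markers rose in 9 and fell in 1 of 22 cases, with 14 changed when adjusted over the list alone (median 0.7, camera adjusted p = 8.49e-05, adjusted p = 0.62 with an estimated correlation). PRP1, a cell wall protein of root hairs, rose from 105 ± 13.4 to 269 ± 4.41, while the nitrate transporter NRT2:1 fell by 1.62 ± 0.19. Cold response genes fell in 8 of 13 cases, with 8 changed when adjusted over the list alone (median -0.77, camera adjusted p = 2.48e-05, adjusted p = 0.62 with an estimated correlation), COR15B and KIN2 by -2.31 and -1.93. Abscisic acid response genes fell in 9 and rose in 1 of 13 cases, 11 changing when adjusted over the list alone (median -0.9, camera adjusted p = 0.00363, adjusted p = 0.62 with an estimated correlation), RD20 from 259 ± 27.9 to 31.6 ± 16.7. Clock genes fell in 11 and rose in 2 of 18 cases, with 13 changed when adjusted over the list alone (median -0.49, camera adjusted p = 0.00119, adjusted p = 0.62 with an estimated correlation). The 2 that rose were LHY, from 51.7 ± 0.803 to 151 ± 8.82, and RVE8, by 0.99 ± 0.11, and among those that fell were FKF1 (-1.03 ± 0.09) and PRR3 (-0.66 ± 0.06).

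Phosphate starvation genes rose in 8 of 15 cases in scs1 scs2a, 10 changing when adjusted over the list alone (median 0.57, camera adjusted p = 2.65e-05, adjusted p = 0.62 with an estimated correlation), SRG3 by 0.65 ± 0.09 and the phosphate transporter PHT1;1 by 0.8 ± 0.12. Touch response genes rose in 2 of 14 cases, TCH3 and WRKY18, by 1.52 ± 0.14 and 1.16 ± 0.11, and 6 changed when adjusted over the list alone (median 0.53, camera adjusted p = 0.00195, adjusted p = 0.62 with an estimated correlation). Flavonoid synthesis genes rose in 7 of 18 cases, 7 changing when adjusted over the list alone (median 0.24, camera adjusted p = 0.0436, adjusted p = 0.635 with an estimated correlation), F3H by 0.97 ± 0.12. Of 19 salicylic acid and defence genes 1 rose by limma, SARD1 (0.46 ± 0.12), and none changed when adjusted over the list alone (median 0.37, camera adjusted p = 0.0435, adjusted p = 0.62 with an estimated correlation). The SARD1 call ended without wild type replicate 1 (adjusted p = 0.103), wild type replicate 2 (0.0838), scs1 scs2a replicate 1 (0.0961) or scs1 scs2a replicate 2 (0.127). The flavonoid call ended without wild type replicate 1 (adjusted p = 0.517), hag1 replicate 1 (0.0711), hag1 replicate 2 (0.0634) or scs1 scs2a replicate 1 (0.0732), and the defence call without wild type replicate 2 (0.132) or scs1 scs2a replicate 1 (0.312).

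The other lists were not called by camera in scs1 scs2a. Higher and lower members, those changed when adjusted over the list alone and the camera adjusted p were 6, 7, 16 and 0.991 for glucosinolate synthesis, 2, 8, 14 and 0.109 for iron deficiency, 2, 5, 7 and 0.506 for early auxin response and 3, 4, 7 and 0.662 for cell wall expansion. They were 4, 1, 5 and 0.214 for heat shock and 2, 1, 3 and 0.887 for senescence. Iron deficiency was called as lower without wild type replicate 1 (adjusted p = 0.0361) or scs1 scs2a replicate 2 (0.0187). In 10 meristem genes 2 fell and 2 changed when adjusted over the list alone (adjusted p = 0.436), in 16 cell division genes 1 fell and 1 changed when adjusted over the list alone (0.442), and in 7 wax genes 2 rose and 2 changed when adjusted over the list alone (0.196). In 20 SAGA subunit genes 1 rose by limma, SGF11, and in 9 trichome genes 1 fell, ETC2, and none changed when adjusted over the list alone (camera adjusted p = 0.148 and 0.577). SGF11 lost its call without wild type replicate 1 (adjusted p = 0.145), wild type replicate 2 (0.0869), scs1 scs2a replicate 1 (0.105) or scs1 scs2a replicate 2 (0.13). ETC2 lost it without wild type replicate 1 (0.0909), wild type replicate 2 (0.145), scs1 scs2a replicate 1 (0.117) or scs1 scs2a replicate 2 (0.148). No ribosomal protein or seed gene passed limma's test, with or without being adjusted over the list alone (camera adjusted p = 0.354 and 0.598). The signs of median, mean and test differed for jasmonate and wounding (-0.05, 0.48, up, 0.577, with 5 higher, 2 lower and 7 when adjusted over the list alone). They differed also for flowering (0.4, -0.06, up, 0.437, with 1 higher, 2 lower and 4 when adjusted over the list alone). Of these lists, FER1 rose by 1.03 ± 0.06, MYB28 fell by 0.57 ± 0.07 and AGL20 fell by 1.17 ± 0.13.

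In scs1 scs2a 2001 genes were higher and 3078 lower, of which 309 and 661 changed at least 2-fold. These counts depended on single libraries. They were 957 and 1649 without wild type replicate 1, 979 and 1870 without wild type replicate 2, and 476 and 1207 without scs1 scs2a replicate 2, and the higher count was 1091 without scs1 scs2a replicate 1.

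**Figure D3:**
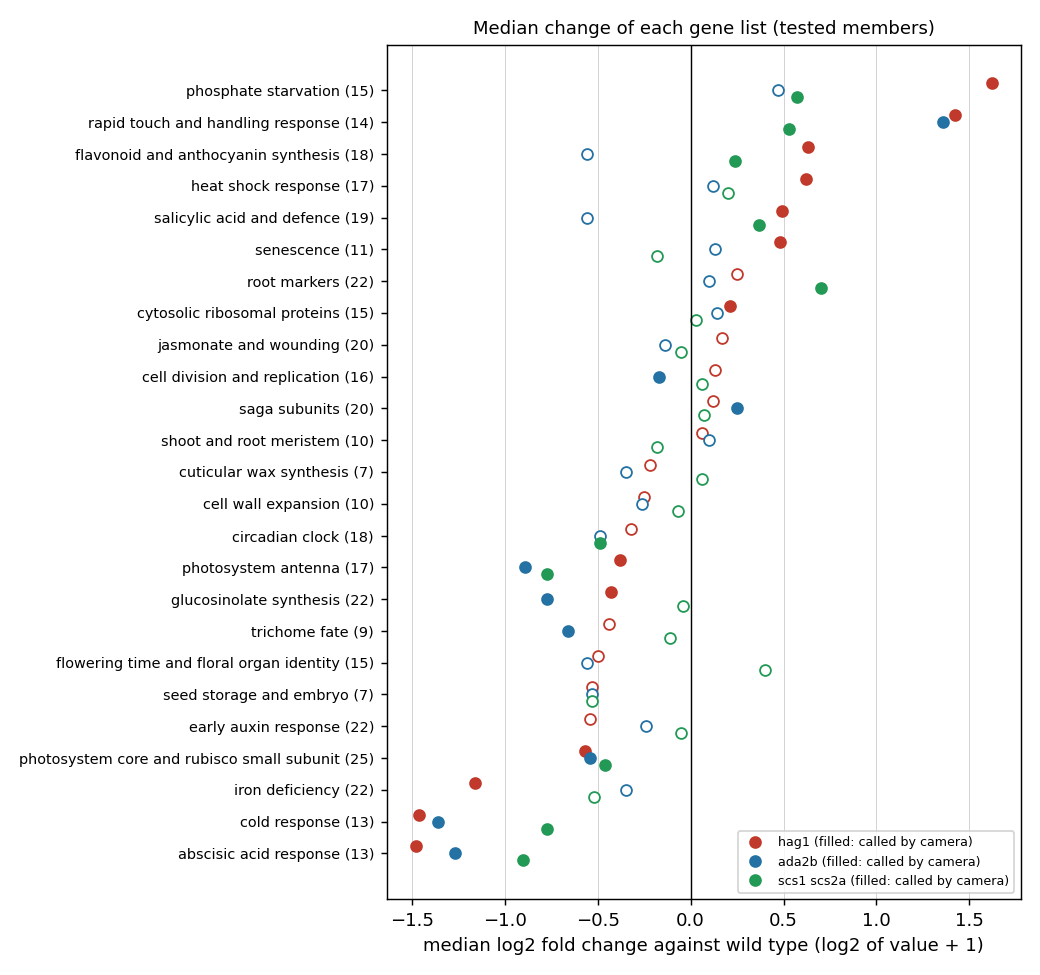
Median log2 fold change of the tested members (number in brackets) of each of 25 gene lists in 3 mutants, filled where camera called the list at adjusted p under 0.05. Photosystem core, cold and abscisic acid lists were filled below 0 in each mutant, and the phosphate starvation medians were 1.62, 0.47 and 0.57.

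The mutants were next compared for likeness. XTH7, which remodels cell walls, rose in all 3, from 3580 ± 105 in wild type to 8120 ± 205 in hag1, 8700 ± 129 in ada2b and 8430 ± 701 in scs1 scs2a. AT3G15356 rose by 2.41, 2.78 and 2.97 in the same order, and AT1G15125 by 0.95, 0.94 and 1.98. AT3G16530 and AT3G16525 rose by at least 1.74 in each. The strand used in counting is not given in the sources used here, so overlapping or antisense genes are uncertain. TGG2, a myrosinase that breaks down glucosinolates, fell in all 3, from 17900 ± 1280 to 1800 ± 266, 1040 ± 30.9 and 5250 ± 292. The aquaporin genes DELTA-TIP (-1.1, -2.22 and -1.4) and TIP2 (-0.78, -1.75 and -0.93), with ZW9 (-0.99, -2.83 and -1.46) and AT4G30650 (-1.03, -2.26 and -1.23), also fell. In all, 1200 genes were higher and 2046 lower in all 3 mutants, which is 60% and 66.5% of the scs1 scs2a calls, and independent lists would share 105 and 166. That expectation takes all genes as equally likely to be called and may be too low. In scs1 scs2a, 3% of genes with means of 1 to 3 were called lower, against 34% with means of 3000 or more. The median log2 fold changes of the shared genes were 0.57, 0.59 and 0.39 for those higher and -0.81, -1.02 and -0.6 for those lower in hag1, ada2b and scs1 scs2a. The shared counts were 651 and 1185 without wild type replicate 1, 652 and 1312 without wild type replicate 2, and 360 and 1002 without scs1 scs2a replicate 2, and 758 were higher without scs1 scs2a replicate 1.

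By pairs, 3064 genes were higher and 3272 lower in both hag1 and ada2b (1337 and 1374 for independent lists), and 892 had opposite directions (2716). For hag1 and scs1 scs2a 1417 were higher and 2451 lower in both (426 and 708), with 136 opposite (1116). For ada2b and scs1 scs2a 1599 were higher and 2515 lower in both (494 and 722), with 85 opposite (1229). In simulations with no gene changed, groups that shared 2 simulated wild type libraries had at most 0.05 calls in common on average over 100 simulations. Few genes are called when none changes, so this value sets no expected overlap for lists of this size. Across genes, which are not independent replicates, Pearson's r was 0.61, 0.61 and 0.7 for these pairs, against 0.5 simulated. The covariance was 0.42, 0.269 and 0.329 against 0.042 simulated, a difference of 0.379, 0.228 and 0.287. The wild type libraries were not split between the mutants, since each part would have held 1 library, so part of the excess in overlap may come from the shared controls. Calls were also more frequent among genes of high level, which can raise the overlap above that of independent lists.

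Between ada2b and hag1, BHLH100 differed, at 240 ± 60.8 in ada2b and 7.56 ± 1.8 in hag1, a log2 difference of 4.81 ± 0.32 (limma adjusted p = 2.64e-05). MAF5 (4.21), CIB5 (3.54) and bHLH38 (3.47) were also higher in ada2b. LURP1, a defence gene, PYD4 and BAM5 were lower by log2 differences of -5.69, -4.53 and -4.24, and the receptor-like kinase CRK4 had an estimated 2 reads in ada2b against an estimated 242 in hag1, a ratio of 0.0081 (95% counting interval 0.000975 to 0.0296). Camera called phosphate starvation genes lower in ada2b than in hag1, 13 of 15 by limma and 14 when adjusted over the list alone (median -1.03, camera adjusted p = 3.21e-07, adjusted p = 0.454 with an estimated correlation). Flavonoid genes were lower in 16 of 18 cases, 16 when adjusted over the list alone (median -0.95, camera adjusted p = 7.28e-05, adjusted p = 0.613 with an estimated correlation). Glucosinolate genes were lower in 15 and higher in 2 of 22 cases, 19 changing when adjusted over the list alone (median -0.35, camera adjusted p = 0.000162, adjusted p = 0.454 with an estimated correlation). Cell division genes were lower in 8 of 16 cases, 8 when adjusted over the list alone (median -0.39, camera adjusted p = 0.00148, adjusted p = 0.406 with an estimated correlation). Iron deficiency genes were higher in 12 and lower in 3 of 22 cases, 18 changing when adjusted over the list alone (median 0.83, camera adjusted p = 0.0165, adjusted p = 0.681 with an estimated correlation). Defence genes were lower in 9 of 19 cases, 10 when adjusted over the list alone (median -0.77, camera adjusted p = 0.00161, adjusted p = 0.585 with an estimated correlation). Senescence genes were lower in 7 of 11, 7 when adjusted over the list alone (median -0.35, camera adjusted p = 0.0113, adjusted p = 0.603 with an estimated correlation), and antenna genes in 7 of 17, 7 when adjusted over the list alone (median -0.22, camera adjusted p = 0.0122, adjusted p = 0.774 with an estimated correlation). Jasmonate genes were lower in 9 and higher in 1 of 20 cases, 10 changing when adjusted over the list alone (median -0.66, camera adjusted p = 0.0222, adjusted p = 0.713 with an estimated correlation). SAGA subunit genes were higher in 8 and lower in 1 of 20, 9 changing when adjusted over the list alone (median 0.14, camera adjusted p = 0.0278, adjusted p = 0.454 with an estimated correlation). In all 5510 genes were higher and 5390 lower in ada2b, 662 and 2058 of them at least 2-fold. These were 4933 higher and 5900 lower under median-ratio scaling and 4923 and 5855 under upper-quartile scaling, so the side with more genes depended on the scaling.

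Between scs1 scs2a and hag1, MAF5 (log2 difference 3.88 ± 0.29, limma adjusted p = 1e-04), PPT2 (3.41), the fucosidase gene FUC1 (3.14) and MAF4 (2.96) were higher in scs1 scs2a. TH8 (-4.09 ± 0.18, limma adjusted p = 1.86e-05), the lipid transfer protein gene LTP2 (-3.61), BAM5 (-3.57) and BGLU28 (-3.51) were lower. Phosphate starvation genes were lower in 13 and higher in 1 of 15 cases, 15 changing when adjusted over the list alone (median -1.17, camera adjusted p = 2.18e-07, adjusted p = 0.454 with an estimated correlation). Iron deficiency genes were higher in 16 and lower in 2 of 22 cases, 18 when adjusted over the list alone (median 0.86, camera adjusted p = 7.36e-05, adjusted p = 0.514 with an estimated correlation). Glucosinolate genes were higher in 11 and lower in 1 of 22 cases, 14 changing when adjusted over the list alone (median 0.31, camera adjusted p = 0.000131, adjusted p = 0.454 with an estimated correlation). Ribosomal protein genes were lower in 4 of 15, 9 when adjusted over the list alone (median -0.17, camera adjusted p = 0.00161, adjusted p = 0.713 with an estimated correlation), and touch response genes in 4 of 14, 5 when adjusted over the list alone (median -0.75, camera adjusted p = 0.00636, adjusted p = 0.713 with an estimated correlation). Senescence genes were lower in 5 of 11, 5 when adjusted over the list alone (median -0.51, camera adjusted p = 0.00683, adjusted p = 0.585 with an estimated correlation), and antenna genes in 6 of 17, 6 when adjusted over the list alone (median -0.28, camera adjusted p = 0.0207, adjusted p = 0.783 with an estimated correlation). Photosystem core genes were higher in 5 of 25 cases, 5 when adjusted over the list alone (median 0.15, camera adjusted p = 0.0327, adjusted p = 0.789 with an estimated correlation). Of 7652 genes called, 3865 were higher and 3787 lower in scs1 scs2a, 793 and 862 of them at least 2-fold. Without scs1 scs2a replicate 1 these were 2111 and 2228, and without scs1 scs2a replicate 2 they were 2426 and 2430.

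Between scs1 scs2a and ada2b, FMO GS-OX2 (log2 difference 3.87 ± 0.46, limma adjusted p = 0.00077), the cellulose synthase-like gene CSLB03 (3.81) and GLP4 (3.79) were higher in scs1 scs2a. LURP1 differed by 4 ± 0.88, a call that ended without scs1 scs2a replicate 2 (adjusted p = 0.081), and LURP1 differed by 2.36 without ada2b replicate 1. BHLH100 (-2.65 ± 0.32, limma adjusted p = 0.000836), ESE3 (-2.34) and the trehalose phosphate synthase genes TPS8 (-2.33) and TPS11 (-2.3) were lower. Glucosinolate genes were higher in 18 of 22 cases, 19 when adjusted over the list alone (median 0.63, camera adjusted p = 1.98e-12, adjusted p = 0.406 with an estimated correlation). Cell division genes were higher in 8 of 16 cases, 9 when adjusted over the list alone (median 0.25, camera adjusted p = 0.000131, adjusted p = 0.406 with an estimated correlation). Of the root markers 5 of 22 were higher, 5 when adjusted over the list alone (median 0.35, camera adjusted p = 0.00161, adjusted p = 0.713 with an estimated correlation). Flavonoid genes were higher in 9 of 18 cases, 9 when adjusted over the list alone (median 0.51, camera adjusted p = 0.000131, adjusted p = 0.647 with an estimated correlation), and defence genes in 6 of 19, 6 when adjusted over the list alone (median 0.59, camera adjusted p = 0.0027, adjusted p = 0.585 with an estimated correlation). SAGA subunit genes were lower in 6 and higher in 1 of 20 cases, 12 changing when adjusted over the list alone (median -0.18, camera adjusted p = 0.0145, adjusted p = 0.454 with an estimated correlation). Cell wall expansion genes were higher in 5 and lower in 1 of 10 cases, 7 changing when adjusted over the list alone (median 0.44, camera adjusted p = 0.0207, adjusted p = 0.454 with an estimated correlation). Trichome fate genes were higher in 4 of 9, 4 when adjusted over the list alone (median 0.9, camera adjusted p = 0.0215, adjusted p = 0.454 with an estimated correlation). In all 3775 genes were higher and 3792 lower in scs1 scs2a, 1496 and 211 of them at least 2-fold. The higher share was 49.9% as deposited, 60.2% with median-ratio scaling and 65.8% with upper-quartile scaling, which moved the median of all genes by 0.03 and 0.05. Without scs1 scs2a replicate 1 the counts were 2193 and 1781, without scs1 scs2a replicate 2 they were 2360 and 1779, and the lower count was 1940 without ada2b replicate 1 and 1736 without ada2b replicate 2.

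**Figure D4:**
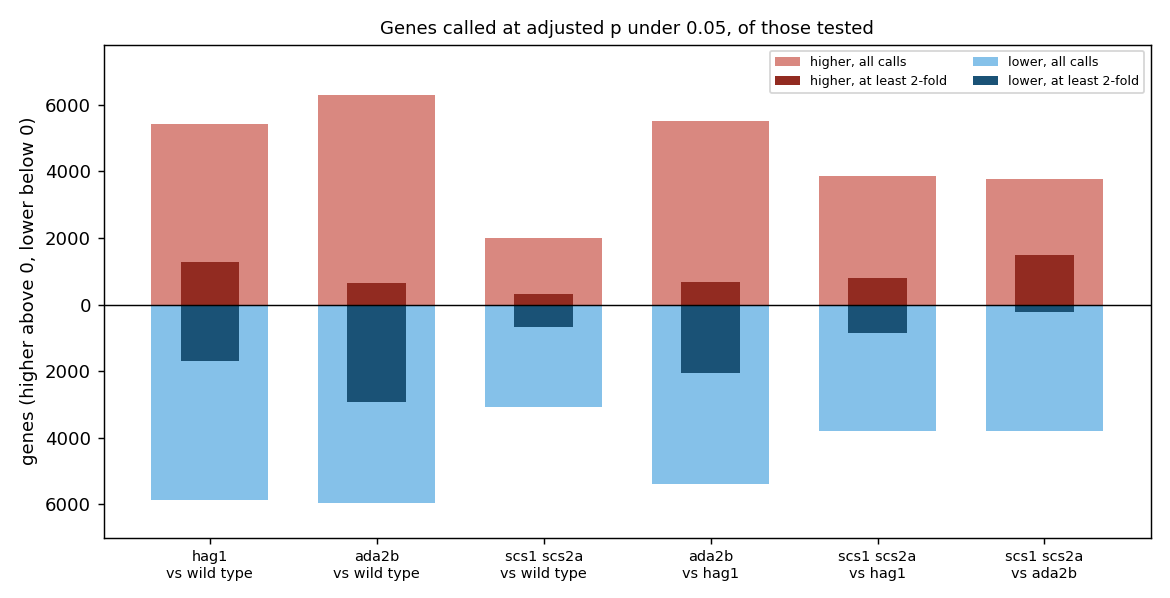
Number of genes called higher (above 0) and lower (below 0) in each comparison at a limma adjusted p under 0.05, with the part changed at least 2-fold in dark. In ada2b against wild type 2940 genes fell at least 2-fold and 644 rose.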

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

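Of the alternatives here, the filter at 10 and the robust spread estimate were chosen after seeing the data. No direction of a named gene, or of a list call against wild type, turned under any alternative run. The list calls between mutants were not rerun with another scaling, a replicate block or a library left out. The fold minimum of 2 left 1276 higher and 1695 lower genes in hag1, 644 and 2940 in ada2b, 309 and 661 in scs1 scs2a, 662 and 2058 for ada2b against hag1, 793 and 862 for scs1 scs2a against hag1, and 1496 and 211 for scs1 scs2a against ada2b, because it asks for more. With no filter, scs1 scs2a had 1018 higher and 1780 lower genes, scs1 scs2a against ada2b had 2464 higher, and 659 higher and 1278 lower were shared by the 3 mutants; the cause was not tested. Upper-quartile scaling gave 2181 lower genes for scs1 scs2a against ada2b; the cause was not tested. With an estimated correlation, 0 lists were called higher and 0 lower in each mutant. Cell division in ada2b lost its call at an estimated correlation of -0.01, where camera's unadjusted p went from 0.00927 to 0.0493. Correlation between members thus does not account for every loss. For a simulated list of 15 independently drawn genes raised 2-fold in hag1, camera's p went from 3.28e-60 to 6.23e-05. The estimated-correlation option, with 4 residual degrees of freedom, thus gave larger p-values even without correlation. How much of each loss this explains was not tested. With fry 11 lists were lower in hag1, 14 lower in ada2b and 3 higher in scs1 scs2a; the cause was not tested. Of 511 calls of named genes, 88 were lost with no filter, 16 with the robust estimate, 24 with only the 2 genotypes compared and 10 with median-ratio scaling. Without either wild type library or scs1 scs2a replicate 2, more were lost than under any of these except no filter.

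Leaving out 1 library at a time, with the lone library assumed to vary like the other groups, gave 4013 to 5242 higher and 4519 to 5719 lower genes in hag1, 4606 to 6299 and 4708 to 6052 in ada2b, and 476 to 2094 and 1207 to 3067 in scs1 scs2a. The ranges were 3946 to 5380 and 4014 to 5212 for ada2b against hag1, 2111 to 3699 and 2228 to 3636 for scs1 scs2a against hag1, 2193 to 3878 and 1736 to 3803 for scs1 scs2a against ada2b, and 360 to 1191 and 1002 to 1970 for all 3 mutants. Lists called were 6 to 7 higher and 5 to 6 lower in hag1, 2 to 4 and 5 to 9 in ada2b, and 3 to 5 and 5 to 6 in scs1 scs2a, with 4 higher in ada2b without ada2b replicate 2 and 3 higher in scs1 scs2a without scs1 scs2a replicate 1. The log2 fold change of HAG1 in hag1 was -1.3 to -1.16 and that of ADA2B in ada2b -0.32 to -0.21. HAG1 in ada2b was 0.34 to 0.48.

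The replicate numbers share only a number, with correlations of replicate deviations between groups of -0.12 to 0.19. With the number as a replicate block, 5162 genes were higher and 5653 lower in hag1, 6019 and 5804 in ada2b, and 1723 and 2779 in scs1 scs2a. The flavonoid list in scs1 scs2a lost its call (adjusted p = 0.0536), and no other list call against wild type changed. A DESeq2 test, limma-voom and edgeR's scaling were not run, since the values are not counts. Genes at 1 to 3 reads are limited by depth.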

Other observations

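The gene families here were tested only after the results were seen, as were the tests of explanations. Gene families named by the reference's product descriptions gave 238 sets and 714 camera tests. Leucine-rich repeat protein kinases fell in 61 and rose in 6 of 113 cases in ada2b (median log2 fold change -0.56, camera adjusted p = 2.23e-06, adjusted p = 0.6 with an estimated correlation) and fell in 55 and rose in 7 in hag1 (median -0.32, camera adjusted p = 0.000524, adjusted p = 0.698 with an estimated correlation). Pectin lyase-like genes, which act on cell walls, fell in 39 and rose in 6 of 62 cases in ada2b (median -1.03, camera adjusted p = 1.01e-05), fell in 30 and rose in 4 in hag1 (-0.43, 0.0053) and fell in 24 and rose in 1 in scs1 scs2a (-0.5, 2.83e-05), each with adjusted p = 0.698 with an estimated correlation. Transcription factors of the bHLH family fell in 51 and rose in 4 of 104 cases in ada2b (median -0.6, camera adjusted p = 2.39e-05, adjusted p = 0.6 with an estimated correlation). In hag1, snoRNA genes rose in 33 and fell in 4 of 249 cases (median 0.53, camera adjusted p = 0.00949, adjusted p = 0.6 with an estimated correlation), against 8 higher and 7 lower in ada2b (adjusted p = 0.935). Of all 25459 genes tested, 5419 rose and 5860 fell in hag1, so called rises and called falls were both less frequent among snoRNA genes. Tetratricopeptide repeat-like genes rose in 82 and fell in 16 of 262 cases in ada2b (median 0.21, camera adjusted p = 0.0118, adjusted p = 0.701 with an estimated correlation). Of all 25459 genes, 6283 rose in ada2b, a smaller share than in this family. Among genes with a mean of 100 or more 34.9% rose, a larger share.

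The 1982 genes with means of 3 to 100 that fell in ada2b had a median log2 fold change of -1.57. Lower depth of the ada2b libraries argues against itself, since their estimated reads were 1.06 times those of wild type. Genomic DNA in the wild type libraries would have left 0.0386% of protein-coding genes without reads at the median loss per kb, and 14.9% of 27444 had 0 reads in both. A smaller share of root tissue would have lowered root markers alike, and the lower quartile of the 22 root markers was -0.24 (median 0.1). A loss of expression of these genes in ada2b is a hypothesis that the design allows, found on the same data and not itself tested.

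There were 78 genes that stood apart in hag1, 51 higher and 27 lower. Each lay 4-fold or more beyond every other genotype and was called against each, while the other genotypes stayed within 2-fold of one another. They include BAM5, GDPD6, CIB5, FUC1, MAF4 and MAF5, which were named above. Of the 78 genes, 7 lay within 500 tested genes of HAG1 against 2.62 expected (a share of 0.019 of 10000 draws). A chromosome segment of another accession around HAG1 is thus a candidate explanation for some of these 7. The window was a chosen setting that does not bound a segment, so the draws do not decide for the other 71. Genes on other chromosomes cannot lie in such a segment, but AT3G47010 and other chromosome 3 genes beyond the window could. Effects of a segment on genes elsewhere were not tested. Among the 7, AT3G51070 and the lncRNA gene AT3G51075 moved alike in hag1 (log2 fold changes -3.33 and -3.17). The draws treated them as separate, so the share may be too small. Several segments cannot be told apart from chance, with 5 neighbouring pairs among all 78 genes, those near HAG1 included, against 2.47 expected (a share of 0.095). Another accession across the genome would have left genes with 0 reads in hag1 alone and means of at least 20 elsewhere, and there were 0 in hag1, as in ada2b and scs1 scs2a. An effect of the hag1 mutation stays open and untested.

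LHY was higher in all 3 mutants. A different time of harvest would have moved LHY and CCA1, which peak together, alike, and LHY exceeded CCA1 by 1.97 ± 0.28, 2.25 ± 0.28 and 1.97 ± 0.28 on the log2 scale in hag1, ada2b and scs1 scs2a. That argues against it as the whole cause for these genes, but CCA1 was chosen after its values were seen. The evening genes PRR3 and FKF1 fell in hag1 and scs1 scs2a, so a part played by the time of harvest stays open. An effect of the mutations is a hypothesis found on the same data.

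A hypothesis for the fall of photosystem genes in the 3 mutants was an energy starvation response, tested on 12 starvation genes, a list chosen after the other results were seen but before the values of its genes were looked at. They rose in 10 of 12 cases in hag1 (median log2 fold change 0.87, camera adjusted p = 9.83e-06, adjusted p = 0.153 with an estimated correlation) and in 11 of 12 in ada2b (median 0.76, camera adjusted p = 5.68e-06, adjusted p = 0.153 with an estimated correlation). Adjusted over the list alone, 10 and 11 changed. In scs1 scs2a 1 of 12 rose, and 1 changed when adjusted over the list alone (median 0.06, camera adjusted p = 0.164, adjusted p = 0.549 with an estimated correlation), so the prediction that it would rise in each mutant was not met there. A larger share of root tissue stays open in hag1 and scs1 scs2a, where root markers had medians of 0.25 and 0.7, but in ada2b, where photosystem core and antenna medians were -0.54 and -0.89, 5 of 22 root markers rose and 3 fell, 7 changing when adjusted over the list alone (median 0.1, mean -0.14, camera adjusted p = 0.859).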
